A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

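Total RNA of Saccharomyces cerevisiae was measured on 8 Affymetrix yeast expression arrays, 2 for a strain labelled parental and 2 for each of 3 strains isolated after growth for approximately 450 generations. Per the labels, the parent was BY4742, a laboratory strain, and cultures of 100 ml were kept at 30 °C in complete medium with 2% glucose and 0.5% ammonium sulfate by daily transfer of 10 µl. Biotin-labelled cRNA was made from 100 ng of total RNA. The labels call the 2 arrays of a group biological replicates and do not say whether they came from separate cultures, so that the p-values measure only the spread between these arrays.

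The deposited values are intensity values made by the authors with RMA, which corrects background, normalises quantiles between arrays and summarises the probes of a probe set; its version is not given in the sources used here. The deposited intensity values were on a linear scale, although a log2 scale had been assumed when the analysis was planned, so log2 was taken here before any further step. Median intensity over all probe sets was 63.0 and 61.0 for the parental arrays, 52.6 and 54.0 for strain 1, 57.4 and 58.2 for strain 2, and 56.5 and 56.2 for strain 3. With 2 arrays per group, the number of arrays limits the precision.

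Of 10928 probe sets, the annotation listed 7245 and did not list 3683. It gave 1 S. cerevisiae gene for 5498 probe sets and several genes for 1, and 1746 belonged to another yeast species on the same array design. The tests used 5449 genes. For the 47 genes with several probe sets, the probe set with the highest mean over all arrays was used. The probe sets called 5 of these 47 genes in opposite directions (ENA5, HXT9, PRM7, RPL14B and YBR219C), and they lay more than 2-fold apart for 6. Gene symbols were updated for 12 genes from the annotation of the R64 assembly, which was used only for names and for the order of neighbours. No probe set of a mitochondrially encoded gene was assigned, so those genes were not analysed here. Background was the 95th percentile of the other-species probe sets on each array, which lay between 4.27 and 4.40 on the log2 scale; 5296 to 5326 genes were above it on each array. For a gene at or below background on every array of one side, fold differences were computed against that level and are given as lower bounds. No fold is given where both sides were at background.

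Differences were tested with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for the robust fit. One model with 1 coefficient per group was fitted to all 8 arrays, which left 4 residual degrees of freedom, and empirical Bayes moderation added a prior of 2.52 degrees of freedom with a standard deviation of 0.0433 on the log2 scale. The contrasts were each evolved strain minus parental, the mean of the evolved strains minus parental, and each pair of evolved strains; a moderated F test asked for any difference among the evolved strains. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. Counts of changes of at least 2-fold are given beside all calls. An exact permutation of 2 arrays against 2 cannot go below p = 0.333, so that single genes have no exact test here. Genes called in every strain with the same sign were set beside 100 simulations of unchanged strains. In each, all 8 arrays were drawn around the gene's mean with the fitted spread, and the 3 strains shared 2 simulated control arrays.

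Before the data were examined, the contrasts, the alternatives, 43 gene lists and the rule for naming genes were fixed. Genes named for the mean contrast were the 10 largest rises and 10 largest falls among called genes whose 6 evolved arrays all lay on one side of both parental arrays. For each strain the 8 largest in each direction were taken by the same rule, and for differences between evolved strains the 4 largest in each direction among genes called against both other strains. In each list up to 4 members with the largest change were named, and every member of the hexose transport, mating type and auxotrophy lists. Genes named outside these rules are said to have been chosen after their values were seen. Lists with at least 4 measured members, 41 in all, were tested with camera against all other genes with a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. The 41 tests of a contrast were adjusted together. The 16 nuclear chromosomes were tested with camera in the same way.

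The calls were tested on simulated data, arrays drawn around each gene's mean with the fitted spreads shuffled between genes. In these data 50 genes per size, 200 in all, were shifted in strain 1. The test called 70% of those shifted by 0.25 on the log2 scale and 100% of those shifted by 0.5, 1 or 2, and 12 of its 197 calls were of unshifted genes. Every group had the same simulated spread, whereas the measured parental arrays differed more from each other than those of an evolved strain. These rates may therefore not hold against parental. The alternatives were quantile normalization and median centring over the tested probe sets, a filter on dim probe sets, probe sets free of related genes, the mean of a gene's probe sets, an intensity trend with a robust prior, a replicate block, a fit of only the compared groups, the strain as a random block, and leaving out each array in turn. The closing section gives their effect. Probe sets for controls, for the other species and without a listed gene were left out of the tests.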

Results

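Transcript levels of 5449 genes were measured on 8 arrays, 2 for the strain labelled parental and 2 for each of 3 strains grown in glucose medium for approximately 450 generations. The comparison asks how the evolved isolates differed from their parent. Levels are given as log2 intensity with the standard deviation over the arrays of a group. The 2 arrays of each evolved strain correlated across genes at r = 0.9993 to 0.9994, and the 2 labelled parental at r = 0.9972. Across genes, arrays of different evolved strains correlated at r = 0.993 to 0.996 and parental with evolved arrays at r = 0.912 to 0.923; genes are not independent replicates.

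BY4742, the strain that the labels name, is of mating type alpha, lacks LYS2 and carries MET17; the levels of LYS2, MET17 and several mating type genes went against this. LYS2, an enzyme of lysine synthesis, was above background on all 8 arrays, at 9.07 ± 0.04 (SD, n = 2) in the arrays labelled parental and 11.48 ± 0.12 (SD, n = 6) in the evolved arrays. MET17, an enzyme of methionine synthesis, reached at most 4.51 and was above background on 2 of 8 arrays. The arrays labelled parental carried high levels of genes specific to the other mating type, a: the a-factor genes MFA1 and MFA2 stood at 12.36 ± 0.0042 and 12.57 ± 0.05 (SD, n = 2), and the alpha-factor receptor gene STE2 at 9.17 ± 0.02. The alpha-factor gene MF(ALPHA)1 stood at 4.08 ± 0.38 there, at background, and at 5.52 ± 0.20 (SD, n = 6) in the evolved arrays. The other 3 alpha-specific genes were above background on all 8 arrays, in the arrays labelled parental at 4.88 ± 0.50 (MF(ALPHA)2), 7.11 ± 0.04 (STE3) and 7.93 ± 0.06 (SAG1; SD, n = 2). URA3 was at background on all 8 arrays. LEU2 was above it on all 8 arrays but near it, at 5.33 ± 0.08 (SD, n = 2) in the arrays labelled parental and 5.29 ± 0.19 (SD, n = 6) in the evolved arrays. HIS3, of which BY4742 lacks only a part, stood at 11.40 and 12.90 in these groups, which does not tell the strains apart.

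**Figure D1:**
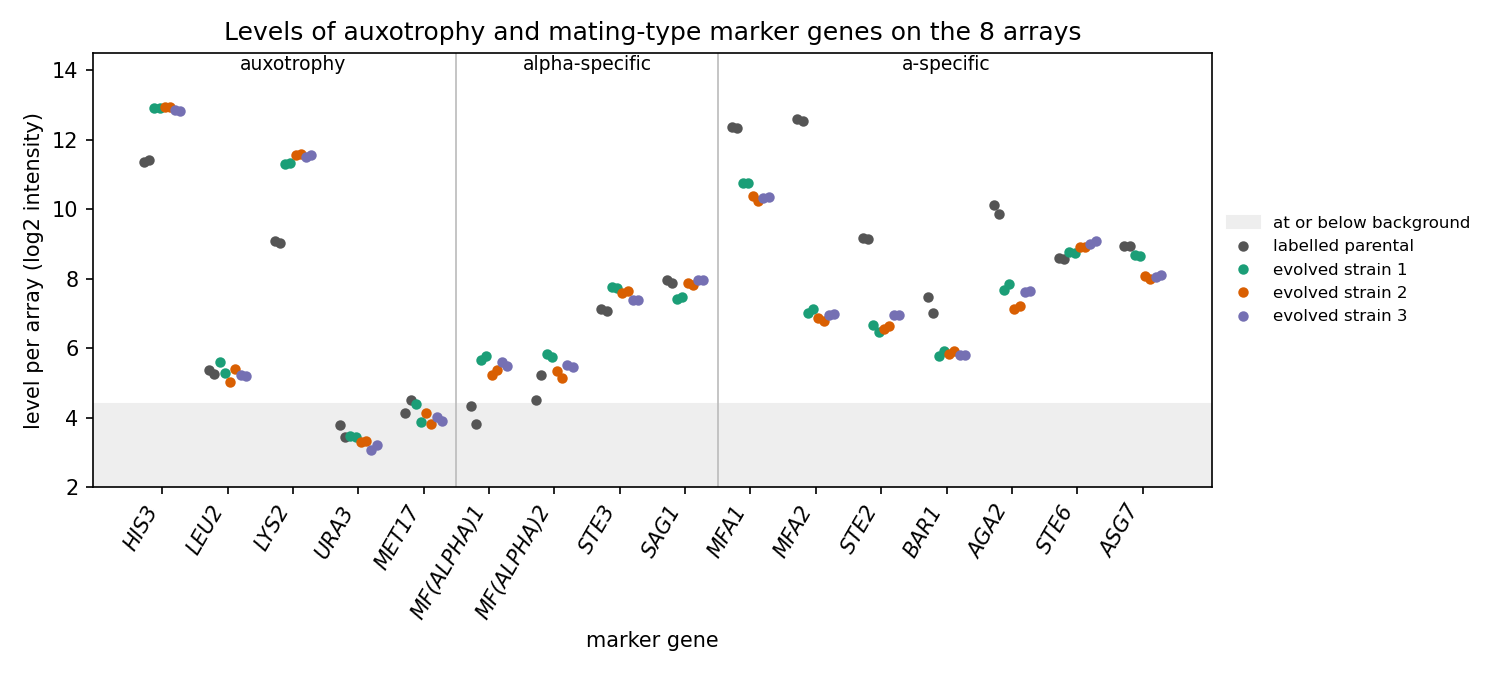
Log2 intensity of auxotrophy, alpha-specific and a-specific marker genes, 1 point per array, coloured by group, with the background range in grey. MFA2 lies at 12.57 in the arrays labelled parental and at 6.96 in the evolved arrays, LYS2 is above background on all 8 arrays, and MET17 is not above 4.51.

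On average over the evolved strains, the genes HXT2, HXT3 and HXT4 (hexose transporters) rose 22.7-fold, 11.7-fold and 10.3-fold, and MFA2, which encodes the mating pheromone of a cells, fell 48.8-fold. The largest rise was of RCK1, a protein kinase gene, by 6.07 ± 0.03 (log2, SE; 2 parental and 6 evolved arrays), or 67.3-fold. SRL4 rose 24.3-fold, PHO5 (secreted acid phosphatase) 15.4-fold, BIO5 (uptake of a biotin precursor) 10.5-fold, ARO4 (first step of aromatic amino acid synthesis) 10.1-fold and YGR035C 10.1-fold. HMLALPHA1, an alpha mating type gene that was at background in the arrays labelled parental, was at least 4.96-fold higher. The log2 differences of the other 9 genes lay between 3.34 and 6.07 with standard errors of at most 0.15, and their adjusted p-values with limma between 5.51e-10 and 2e-07.

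After MFA2, at -5.61 ± 0.04 (log2, SE), the largest falls were of YMR175W-A (32.5-fold) and YKL068W-A (22.9-fold). SSA3, an Hsp70 chaperone gene, fell 18.8-fold, MEP2 (ammonium permease) 15.1-fold, YKL107W 14.8-fold, STE18 (subunit of the pheromone-signalling G protein) 12.8-fold, BTN2 12-fold and ECM2 (splicing factor) 11.9-fold. NEJ1, which acts in non-homologous end joining, was at background on all evolved arrays and at least 13.8-fold lower. Of the 5449 genes, 4725 were called, 2359 higher and 2366 lower; 592 rose and 542 fell by at least 2-fold, 20.8% of genes together. For 2075 rises and 2116 falls the 6 evolved arrays all lay on one side of both parental arrays, which chance gives for 3.57% of genes in each direction if the arrays are independent and for up to 25% if the 4 strains are the units, as the closeness of the arrays within a strain requires. The count fell to 3096 when the strain was a random block.

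**Figure D2:**
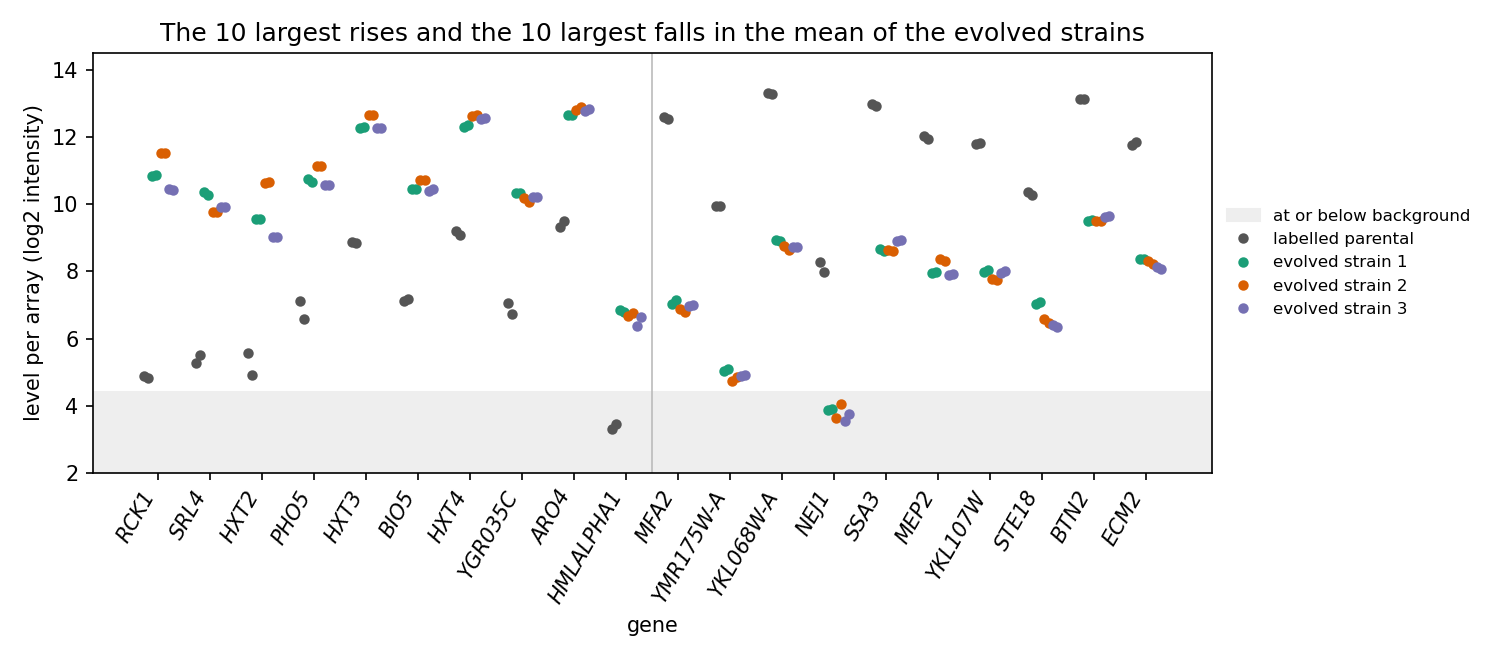
Log2 intensity (vertical axis) of the 10 genes with the largest rises and the 10 with the largest falls in the mean of the evolved strains, 1 point per array, coloured by group, with the background range in grey. RCK1 lies at 4.87 in the arrays labelled parental and at 10.94 in the evolved arrays, and NEJ1 is at background on every evolved array.

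The evolved strains changed largely together. In all 3 strains, 1919 genes were called higher and 1960 lower, against 405 and 419 for independent lists of the same sizes, and 456 and 420 did so by at least 2-fold. In 100 simulations of unchanged strains sharing 2 simulated control arrays, no gene was called in all of them. With no strain changed, few calls can arise at all, so that this count does not show whether strains changed together. Log2 differences from parental correlated between strains at r = 0.959 to 0.977 across genes, where the simulated unchanged strains gave 0.503. The mean covariance of these differences was 0.763 against 0.00217 in the simulations. The controls were the same 2 arrays throughout and cannot be split between strains, so that a shift of these 2 arrays alone would appear in all 3 strains. Genes called in opposite directions in different strains numbered 185, none of them 2-fold in both. RNA quality controls also moved with this comparison: the difference between 3' and 5' probe sets was larger in the arrays labelled parental for 5 of 7 control transcripts and larger in the evolved arrays for 2, with a median of -0.26 (evolved minus parental, log2). The same arrays stand behind every list result.

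All 16 measured glycolysis genes rose, with a median log2 difference of 1.14. The largest rises were of ENO2 (enolase) at 1.87 ± 0.06 (log2, SE), PGI1 (phosphoglucose isomerase) at 1.63 ± 0.02, and the pyruvate kinase genes PYK2 and CDC19 at 1.56 each. The list was called by camera with an adjusted p = 1.72e-05, and the call was lost at adjusted p = 0.072 with an estimated correlation. Of 14 ethanol and acetate genes, 10 rose, among them ADH5 by 2.21 and PDC1 by 2.00, and 4 fell (median 0.53, adjusted p = 0.191). In the hexose transport list, 8 of 23 genes rose, 7 fell and 8 were not called. Besides HXT2, HXT3 and HXT4, these were HXT1 (4-fold), STD1 (glucose signalling, 8.38-fold), MIG1, MIG2 (glucose repressors) and MTH1, while HXT13, HXT15, HXT17, HXT5, HXT9, MIG3 and RGT1 fell. HXT7, at 13.81 in the arrays labelled parental and so near the upper end of the array range, differed by -0.04 ± 0.03 and was not called. Some genes named below lay higher still in these arrays, such as GRE1 (14.16 and 14.21), COX5A (14.07 and 14.10) and FES1 (13.98 and 13.90). Their falls may be understated. The list's median was -0.03 (0.0097 under quantile normalization over the tested probe sets), its mean 0.65 and its test pointed up (adjusted p = 0.809); HXT8, HXT10, HXT14 and HXT15 were at background on both sides. HXT9 is called in opposite directions by its probe sets. Gluconeogenesis and glyoxylate genes showed 5 rises and 12 falls of 20 (median -0.18, adjusted p = 0.191), with SFC1 at -3.20 and FBP1 at -2.01 but ATO3 at 3.03.

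Genes of mitochondrial respiration and translation fell. In the respiratory chain list, 34 of 36 genes fell, with a median of -0.60, as in ATP3 (-0.99 ± 0.03) and COX5A (-0.94 ± 0.02); NDE2, an external NADH dehydrogenase, rose by 0.90. Its adjusted p with camera was 7.94e-07, and adjusted p = 0.0697 with an estimated correlation. Of 68 mitochondrial ribosome genes, 55 fell and 8 rose (median -0.52), as in MRPL51 (-1.38) and MRPS8 (-1.23). That list had an adjusted p = 4.21e-06, and adjusted p = 0.0697 with an estimated correlation. In the tricarboxylic acid cycle 11 of 16 fell and 2 rose (median -0.28, adjusted p = 0.0705), among them CIT3 at -1.22 and LSC1 at 1.13. The retrograde response list had 9 falls and 3 rises of 14 (median -0.34, adjusted p = 0.109).

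Cytosolic ribosomal protein genes rose: 118 of 128 were higher and 6 lower, with a median of 0.83. RPL9A rose by 2.85 ± 0.05 (log2, SE), RPL22A by 2.36 ± 0.02 and RPL5 by 2.21 ± 0.02. This was the only list of the 41 called with both settings in the mean contrast, at adjusted p = 6.85e-16, and at adjusted p = 0.0233 with an estimated correlation. Ribosome biogenesis genes went both ways, 44 up and 26 down of 73 (median 0.31, adjusted p = 0.23), from UTP10 at 1.98 to RPA12 at -2.59. Of 59 amino acid synthesis genes 49 rose and 10 fell (median 1.12), including ILV3 (5.91-fold), LYS9 (5.7-fold) and ARG1 (5.5-fold). This list had an adjusted p = 1.24e-06, and adjusted p = 0.105 with an estimated correlation. Purine and pyrimidine synthesis genes rose in 22 of 29 cases and fell in 6 (median 0.30, adjusted p = 0.0257, and adjusted p = 0.194 with an estimated correlation). IMD3 and GUA1, both of guanine nucleotide synthesis, rose 5.85-fold and 4.47-fold, and IMD2, at background in the arrays labelled parental, was at least 2.56-fold higher.

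Sulfur assimilation and methionine genes fell in 25 of 38 cases and rose in 10 (median -0.56). MET16 fell 7.98-fold and MET14 5.36-fold, both of sulfate assimilation, and SAM4 rose 6.15-fold. The list had an adjusted p = 0.0178, and adjusted p = 0.282 with an estimated correlation. Chaperone genes of the heat shock response fell in 21 of 25 cases (median -0.91); besides SSA3 and BTN2, CPR6 fell 4.2-fold and FES1 3.53-fold. The adjusted p was 0.000126, and adjusted p = 0.132 with an estimated correlation. Trehalose and glycogen genes rose in 17 of 21 cases (median 1.06), as in GSY1 (glycogen synthase, 5.34-fold), GPH1 (glycogen phosphorylase, 3.77-fold) and TPS3 (3.47-fold). Their adjusted p was 0.000501, and adjusted p = 0.282 with an estimated correlation. Phosphate starvation genes rose in 16 of 18 cases (median 0.81), PHM6 by 7.24-fold and the phosphate transporter PHO84 by 5.12-fold, while PHM7 fell 3.48-fold. Their adjusted p was 0.000455, and adjusted p = 0.282 with an estimated correlation. Ergosterol genes rose in 21 of 27 cases (median 0.65), ERG4 by 3.97-fold and ERG26 by 2.66-fold. Their adjusted p was 0.00218, and adjusted p = 0.118 with an estimated correlation.

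Lists of a-specific and of haploid mating genes were lower. Of 7 a-specific genes 6 fell and STE6 rose by 0.32 ± 0.03, with a median of -1.89: AGA2 fell 5.52-fold, STE2 5.49-fold, MFA1 3.7-fold, BAR1 2.64-fold and ASG7 1.6-fold. The list had an adjusted p = 0.034, and adjusted p = 0.332 with an estimated correlation. Of 16 genes on in haploid cells and off in a/alpha diploids, 12 fell, 2 rose and 2 were not called (median -1.10, and -1.11 with background genes at their bound). STE5 fell 5.45-fold, MSG5 4.88-fold and FUS3 4.39-fold, and FAR1, at background in all evolved arrays, was at least 3.29-fold lower. This list had an adjusted p = 0.0293, and adjusted p = 0.218 with an estimated correlation; its call was also lost under quantile normalization over the tested probe sets, with a median of -1.12. Of the 4 alpha-specific genes 3 rose and SAG1 fell by 0.18 on the log2 scale (median 0.55, adjusted p = 0.574). MF(ALPHA)1 was at least 2.23-fold higher, MF(ALPHA)2 rose by 0.63 ± 0.17 and STE3 by 0.48 ± 0.03. Of the 41 lists, 13 were called in the mean contrast, 7 higher and 6 lower. Adjusted over the list alone, the number of called genes in the mean contrast was the same in each list as over all genes tested. In single strains it changed in a few lists, as in the sulfur list in strain 1 (26 falls, and 27 over the list alone).

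**Figure D3:**
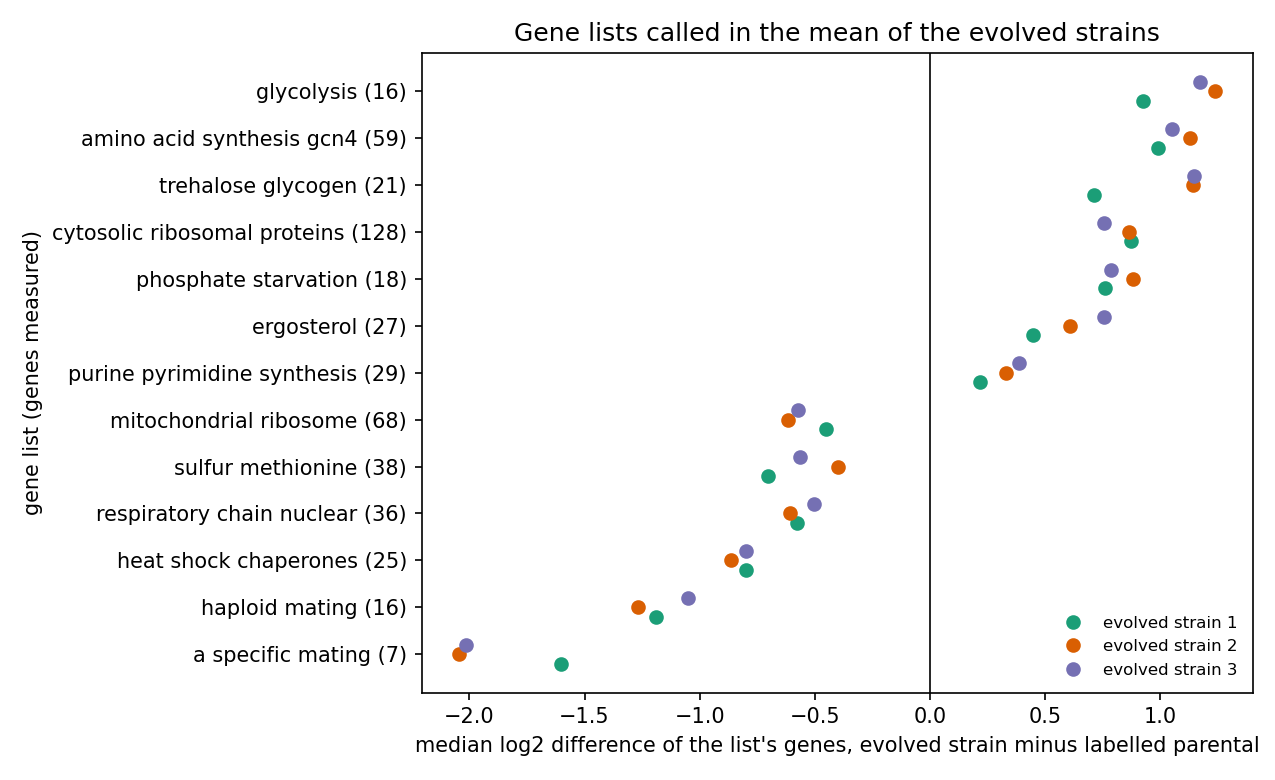
Median log2 difference from the arrays labelled parental (horizontal axis) of the genes in each of the 13 lists called in the mean of the evolved strains, 1 point per strain. In each of these lists the 3 strains lie on the same side of 0, from the a-specific genes (median -1.89 in the mean) to glycolysis (1.14).

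In evolved strain 1, RCK1 rose by 5.99 (log2), SRL4 by 4.91, HXT2 by 4.32, PHO5 by 3.84, YGR035C by 3.44, HXT3 by 3.43 and BIO5 by 3.30, and HMLALPHA1, at background in the arrays labelled parental, was at least 5.47-fold higher. Genes that fell were MFA2 (-5.48), YMR175W-A (-4.88), YKL068W-A (-4.37), SSA3 (-4.33), MEP2 (-4.02), YKL107W (-3.80) and BTN2 (-3.62), and NEJ1, at background, was at least 13.3-fold lower. Standard errors (2 arrays against 2) of these genes were at most 0.19, and adjusted p-values with limma at most 9.25e-07. In total 4606 genes were called, 2214 higher and 2392 lower, with 553 and 561 of at least 2-fold. Of the 41 lists 15 were called, 7 higher and 8 lower, and 1 with an estimated correlation, the cytosolic ribosomal proteins (adjusted p = 0.0174). Called here and not in the mean contrast were the tricarboxylic acid cycle list (13 of 16 fell, median -0.41, adjusted p = 0.0133, and adjusted p = 0.327 with an estimated correlation) and the retrograde response list (10 of 14 fell, median -0.46, adjusted p = 0.0397, and adjusted p = 0.222 with an estimated correlation). Whether lists differed between the evolved strains was not tested.

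In evolved strain 2, RCK1 rose by 6.65 (log2), HXT2 by 5.41, SRL4 by 4.37, PHO5 by 4.28, AAH1 (adenine deaminase) by 3.95, HXT3 by 3.79, BIO5 by 3.58 and HXT4 by 3.49. Genes that fell were MFA2 (-5.74), YMR175W-A (-5.15), YKL068W-A (-4.60), SSA3 (-4.33), YKL107W (-4.05), STE18 (-3.80) and MEP2 (-3.65), and NEJ1, at background, was at least 13.8-fold lower. Standard errors of these genes were at most 0.19, and adjusted p-values with limma at most 3.49e-07. In total 4636 genes were called, 2316 higher and 2320 lower, with 651 and 583 of at least 2-fold. Of the 41 lists 15 were called, 9 higher and 6 lower, and 1 with an estimated correlation, the cytosolic ribosomal proteins (adjusted p = 0.0208). Called here and not in the mean contrast were ribosome biogenesis (45 of 73 rose, median 0.43, adjusted p = 0.0403, and adjusted p = 0.339 with an estimated correlation) and the cell wall integrity list (19 of 32 rose, median 0.55, adjusted p = 0.0403, and adjusted p = 0.288 with an estimated correlation).

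In evolved strain 3, RCK1 rose by 5.57 (log2), SRL4 by 4.52, HXT2 by 3.78, PHO5 by 3.71, HXT3 by 3.42, HXT4 by 3.40, ARO4 by 3.38 and YGR035C by 3.34. Genes that fell were MFA2 (-5.60), YMR175W-A (-5.04), YKL068W-A (-4.58), MEP2 (-4.09), SSA3 (-4.05), STE18 (-3.96) and YKL107W (-3.82), and NEJ1, at background, was at least 14.2-fold lower. Standard errors of these genes were at most 0.19, and adjusted p-values with limma at most 1.69e-06. In total 4585 genes were called, 2343 higher and 2242 lower, with 589 and 541 of at least 2-fold. Of the 41 lists 13 were called, 7 higher and 6 lower, and 1 with an estimated correlation, the cytosolic ribosomal proteins (adjusted p = 0.0335).

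Among the evolved strains, the largest difference was in PRP16, an RNA helicase of splicing. Its level was 11.78 ± 0.04 (SD, n = 2) in strain 1, against 8.17 ± 0.0014 and 8.27 ± 0.0045 in strains 2 and 3 and 8.68 ± 0.02 in the arrays labelled parental, an 11.8-fold difference from the mean of the other evolved strains. GIC2 (a Cdc42 effector), MPT5 (an RNA-binding protein) and MGA1 were lower in strain 1 than in both others, by 1.99-fold, 1.85-fold and 1.81-fold. Strain 2 had the highest levels of FDH1 (formate dehydrogenase, 2.66-fold above the mean of the others), HXT2 (2.56-fold) and HXT1 (2.42-fold). Strain 3 had the lowest of HXT1 (2.17-fold), HXT2 (2.11-fold), AAH1 (2.06-fold) and ZPS1 (1.91-fold), and the highest of HBT1 (1.59-fold) and SHH3 (1.56-fold). These folds are from the mean of strains 1 and 2. HXT1, HXT2, AAH1 and ZPS1 were highest in strain 2, as in HXT2 at 9.56 and 9.55 in strain 1, 10.62 and 10.67 in strain 2 and 9.02 in strain 3. In strain 3, 0 genes were at least 2-fold lower than in both others. YKL096C-B was 1.74-fold higher in strain 1. HXT2 in strain 3 lost its call without any 1 of the 6 evolved arrays, at -1.09 to -1.07 (log2) from the mean of the others, and YKL096C-B in strain 1 without the first array of strain 1 (0.64) or of strain 3 (0.76). YAL037C-A was above background only in strain 2, on 2 of 6 evolved arrays, at 4.94 ± 0.07 (SD, n = 2). For the genes named here, adjusted p against each other evolved strain lay between 2.77e-08 and 0.0455.

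Neighbouring genes of chromosome III were lower in strain 2. Of 11 consecutive measured genes, from MAK32 to RHB1, 10 were lower in strain 2 than in both other evolved strains, with a median of -0.90 (log2) from the mean of those strains. On this scale MAK32 stood at -1.10, SLM5 at -1.04 and NPP1 and HTL1 at -1.02 each. The exception was HSP30, at 0.01 from strain 1. Against the arrays labelled parental, the 11 genes in strain 2 ranged from -1.89 (PET18) to 0.52 (PMP1), with YCR024C-B at -0.03 and YCR023C at -0.11. The genes on either side, SRD1 and FEN2, differed by 0.41 and 0.30. The run of genes, and members outside the naming rule, were chosen after their values were seen.

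**Figure D4:**
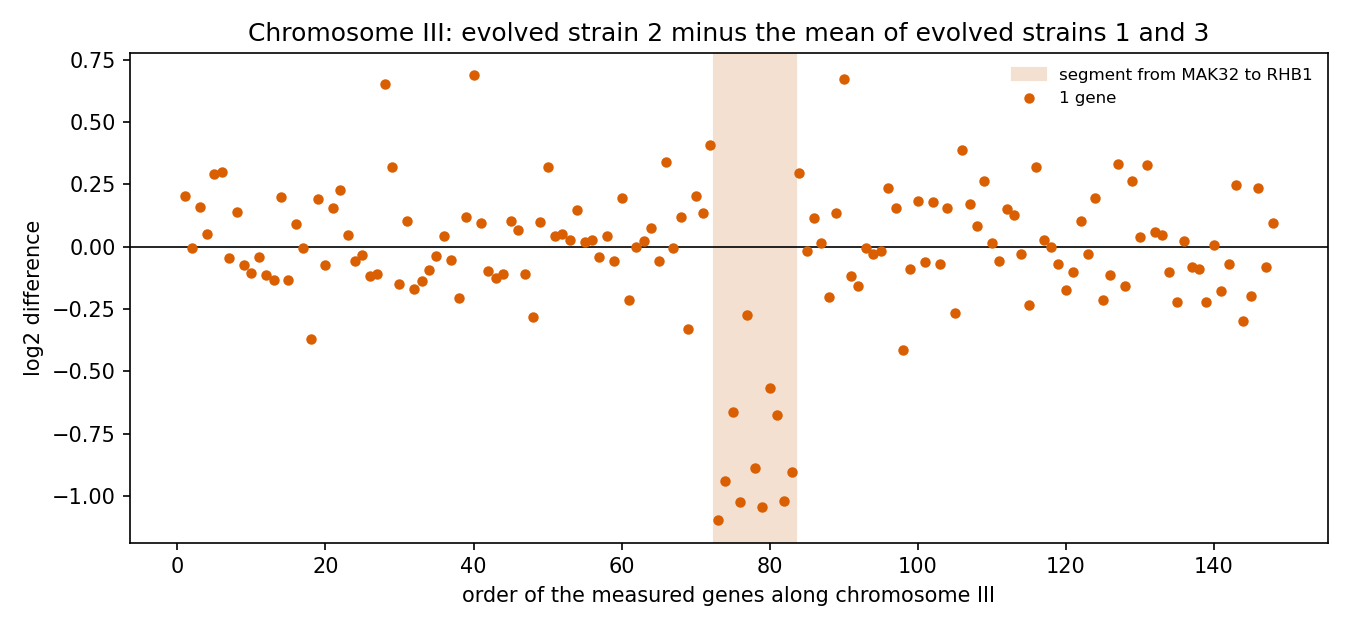
Log2 difference between evolved strain 2 and the mean of strains 1 and 3 (vertical axis), 1 point per gene, for the 148 measured genes of chromosome III in their order along the chromosome. The shaded run from MAK32 to RHB1 has a median of -0.90.

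Between strains 1 and 2, 2873 genes were called, 1625 higher in strain 2 and 1248 lower, of which 7 and 5 by at least 2-fold. Between strains 1 and 3, 3132 genes were called, 1804 higher in strain 3 and 1328 lower, of which 1, PRP16, by at least 2-fold, and 2 genes under quantile normalization, under median centring and without the second array of strain 1. Between strains 2 and 3, 1744 genes were called, 953 higher in strain 3 and 791 lower, of which 4 and 9 by at least 2-fold. The higher share between strains 1 and 2 changed from 56.6% to 39.1% with each array centred on its median, and between strains 1 and 3 from 57.6% to 44.3%. Between strains 2 and 3, leaving out either array of strain 2 gave 760 or 789 calls and either array of strain 3 gave 795 or 825, and the higher share changed from 54.6% to between 42.8% and 46.9%. The F test called 3756 genes among the evolved strains (68.9%), 21 of them with a range of at least 2-fold. Higher or lower than both others were 871 and 1164 genes in strain 1, 407 and 357 in strain 2, and 556 and 403 in strain 3.

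No chromosome was called as moving as a whole. Chromosome medians lay between -0.12 and 0.21 (log2), the highest being chromosome III in strain 2. Single arms, which were not tested, ranged more widely. The right arm of III stood at 0.34, 0.32 and 0.38 in strains 1, 2 and 3, its left arm at 0.07, 0.15 and 0.07. The lowest arm median was -0.29, on the left arm of XII in strain 1. Of 48 tests of 16 chromosomes in 3 strains, camera called 0, 1 was at an unadjusted p under 0.05 (chromosome III in strain 1, median 0.18, adjusted p = 0.79), and 0 were called with an estimated correlation; fry, which does not compare a chromosome with the others, called 41.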

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

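The tests of a mixture of haploid cells, of the marker genes and of the chromosome III genes, and the comparison of single pathway genes with the median of the a1-alpha2 targets, were chosen only after the results they concern had been seen.

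The lists of haploid and of a-specific mating genes had lower medians in all 3 evolved strains than in the arrays labelled parental, though not every member fell. A mixture of a and alpha haploid cells would keep genes on that both types express, which is argued against by the haploid list (median -1.10; 12 of 16 fell and 2 rose); for the a-specific genes it cannot be told apart, since no array of alpha cells shows what MF(ALPHA)1, at 5.52 in the evolved arrays, would reach. A fall shared by all transcripts of the pheromone pathway is argued against by 7 genes of that pathway. The a1-alpha2 repressor does not control these 7 (median -0.14, where 4 fell, BEM1 the most at -1.05, and 2 rose). All 7 lay above the median of the 10 targets. Whether these 7 respond to pathway activity or to growth stage was not tested, so that weaker signalling alone and a later growth stage stay open. The 10 targets of the repressor all fell in the mean of the evolved strains, STE4 at only -0.12 and not in strain 1 (0.04), with a median of -1.48, below all of 10000 expression-matched random lists, although 7 of them belong to the haploid list whose median had been seen; HO, AXL1 and RDH54, outside that list, changed by -1.24, -0.81 and -2.12. These falls could come from a1 and alpha2 acting in the same cells, as in diploids. That would not explain STE6, which alpha2 represses and which rose by 0.32. On the evolved arrays the targets ranged from FAR1, at background, to RME1, at 11.64 or higher, and the a-specific MFA1 stayed at 10.25 or higher. No array of known diploid cells shows what these probe sets would read under repression, so that these levels do not decide it. HMLALPHA1, which the repressor also controls, was at background in the arrays labelled parental, so that its rise of at least 4.96-fold decides nothing on repression. HMRA1 (-1.35, but at 11.84 or higher in the evolved arrays) and HMRA2 (-0.88) were lower. They decide nothing either, since the copies of mating type genes were not measured. The source of alpha2, a strain difference between the groups and evolution in glucose were not tested.

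Marker genes went against the name BY4742 in the arrays labelled parental. A strain of mating type a with LYS2 in all cultures would account for LYS2, at 9.04 or higher on all 8 arrays, and for the 7 a-specific genes above background on both arrays labelled parental, but not for MF(ALPHA)2, STE3 and SAG1, which were above it too. BY4742 cultures that hold a minority of other cells cannot be told apart from such a strain of mating type a. MET17, HMLALPHA1 (3.38) and MF(ALPHA)1 (at no more than 4.35) go against these cultures. MF(ALPHA)2, STE3 and SAG1 go with them only in being above background. No array of known a or alpha cells shows what the probe sets would read. Probe sets for MET17 and LYS2 that do not report their gene cannot be told apart either for these 2 genes, since MET17 at no more than 4.51 has no strain known to carry it among the arrays. It stays open whether the evolved strains descend from the cells on the arrays labelled parental.

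The run of 11 genes of chromosome III from MAK32 to RHB1 was lower in evolved strain 2, HSP30 excepted against strain 1, with a median of -0.90 from the mean of strains 1 and 3, a difference tested gene by gene. Chance neighbours are argued against: the best window of 10 genes had a mean of -0.82, and permutation of the gene order reached at most 0.50 in size (permutation p = 0.0001, the smallest that 10000 orders can give). That median is consistent with loss of 1 of 2 copies, although single genes ranged from -1.10 to -0.27, and against parental from -1.89 to 0.52, and the run was chosen after its values were seen, so that the number of lower genes and the ends of the run count for nothing. Shared regulation of the neighbours cannot be told apart from it. Against parental, counting differences of more than 2 standard errors, these genes went both ways in strain 1 (5 up, 4 down, median 0.10). They did so in strain 3 too (4 up, 5 down, median 0.0076), and neither result decides anything. The bound of this test was rewritten after the value in strain 1 had been seen. DNA copy number was not analysed here.

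Other genes differed between the evolved strains by the test of the difference itself, in log2 units from the mean of the other evolved strains. In strain 1, PRP16 was higher by 3.56, while none of its 6 neighbours was higher by more than 0.45. HTL1 and RHB1 were higher there by 1.20 and 0.90, which includes their fall in strain 2, and YKL096C-B by 0.80. Lower in strain 1 were GIC2 (-0.995), MPT5 (-0.89) and MGA1 (-0.85). Strain 2 had higher FDH1 (1.41), HXT2 (1.36) and HXT1 (1.27), and lower MAK32 (-1.10), SLM5 (-1.04), HTL1 (-1.02) and NPP1 (-1.02), the last 4 in the chromosome III run. Strain 3 had higher YCR023C (0.69) and NPP1 (0.68), which include the fall in strain 2, HBT1 (0.67) and SHH3 (0.65). It had lower HXT1 (-1.12), HXT2 (-1.08), AAH1 (-1.05) and ZPS1 (-0.93), which include their higher levels in strain 2. Calls were lost for HXT2 in strain 3 without any 1 of the 6 evolved arrays (-1.09 to -1.07), for NPP1 in strain 3 without any 1 array of strains 1 and 3 (0.67 to 0.69) and for YKL096C-B without the first array of strain 1 (0.64) or of strain 3 (0.76). YAL037C-A was above background only in strain 2 (4.94), so that its fitted values of -1.34 in strain 1 and 1.49 in strain 2 are not measured sizes.

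A signal outside the gene tests was in the ribosomal RNA control probe sets. The probe set for the 3' part of 18S rRNA was higher in the evolved arrays by 1.23 (log2), above both parental arrays on all 6 of them; the parental arrays read 8.02 and 9.23, and without either the difference was 0.63 or 1.84. The other probe sets differed by these values: 18S 5' part -0.34, 18S middle -0.46, 25S 5' part -0.75, 25S middle -1.43, 25S 3' part 0.0056 and 5.8S -1.54, where 25S 5' part gave -0.48 or -1.02 without either parental array. All of these except the 25S 3' part lay below both parental arrays on all 6 evolved arrays. The falls of 5.8S and of the 25S middle part were larger in size than the rise of the 18S 3' part.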

How the results depend on the processing

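No alternative was added after the data were seen. Against parental, 277 gene results under 4365 alternatives in all kept direction and side of the threshold in 4292, were weaker in 45, stronger in 12 and reversed in 16; the 24 between-strain results did so in 346 of 358 and were weaker in 12 (HXT2 and NPP1 in strain 3 and YKL096C-B in strain 1, each without 1 array, in 6, 4 and 2 cases). The 41 lists did so in 480 of 532. Where an array was left out of a group, the lone array was assumed to vary like the others. The SD of the difference between the 2 arrays was 0.165 (log2) for parental and 0.074 to 0.082 for the evolved strains. Pooled standard errors may be too small against parental and too large between evolved strains. A fit of only the compared groups gave 2432 calls between strains 2 and 3. Against parental it gave 4371, 4436 and 4349 in strains 1, 2 and 3. Among arrays left out, a parental array gave the most calls between strains 2 and 3, though outside that contrast. With an estimated correlation 1 list was called in each of strain 1, strain 2, strain 3 and the mean; with fry, 40, 41, 39 and 39 lists and 41 chromosome tests, since fry does not compare a list with other genes. Calls in the mean contrast numbered 3096 with the strain as a random block (consensus correlation 0.854), which counts the spread between strains as error. That fit used 1 correlation for all genes and took its degrees of freedom from the arrays, so that strains were not its units. Between strains 1 and 3, 2 genes differed 2-fold under quantile normalization and under median centring, and 1 to 2 when an array was left out. Between strains 2 and 3, leaving out an array gave 760 to 2559 calls, 760 and 789 without the arrays of strain 2, 795 and 825 without those of strain 3; the cause was not tested.

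Replicate numbers did not pair the arrays: deviations within groups correlated at -0.12 to 0.03. With the replicate as a block, calls numbered 4580 in strain 1, 4595 in strain 2, 4550 in strain 3, 4707 in the mean, and 2775, 3058 and 1550 between strains 1 and 2, 1 and 3, and 2 and 3.

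Most reversed values lay near 0 and the cause was not tested. Under quantile normalization these were the hexose transport (0.0097), unfolded protein (-0.054), flocculation (0.023) and histone (-0.056) lists, and YAL037C-A (0.020), LEU2 (0.21) and SNF3 (0.0097, the hexose list's median gene); under median centring, HXT10 (-0.030) and HXT11 (-0.0067). Leaving out 1 array gave -0.046 to 0.056 for the unfolded protein list, -0.036 to 0.13 for thiamine, -0.040 to 0.021 for histones, -0.072 to 0.0080 for flocculation, -0.26 to 0.074 for YAL037C-A, -0.093 to 0.027 for LEU2, -0.28 to 0.033 for CDC24, -0.030 to 0.087 for HXT10 and -0.15 to 0.25 for HXT11. Called genes reversed were ENA5 and HXT9. ENA5 was at -1.66 with the probe set used in the tests and at 0.48 without probe sets shared by related genes. HXT9 was at -0.19 in the tests and at 0.028 with its probe sets averaged. Each reversal follows from other probe sets of the gene. The higher share between strains 1 and 2 was 56.6%, 48.0% under quantile normalization and 39.1% under median centring. The a1-alpha2 targets moved from -1.48 to -1.24 without 125 dim genes, -1.38 under quantile normalization and -1.53 under median centring; the chromosome III median stayed between -0.94 and -0.87. Signal over background limits the folds of 21 genes at background in all evolved arrays alone and 22 in the parental arrays alone.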

Other observations

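No test in this part was chosen after its result was seen; IME1 and HMRA1 were looked at after the mating genes. Several lists that were not called held large changes in both directions. Genes of the iron list, which holds biotin uptake genes too, rose in 12 and fell in 11 of 30 cases (median 0.03, adjusted p = 0.665), with VHT1 (biotin permease) up 4.83-fold beside BIO5. In the nitrogen catabolite list 18 of 37 genes rose and 17 fell (median 0.15, mean -0.27, test down, adjusted p = 0.934), from APE1 (4.74-fold up) to DAL2 (5.22-fold down) and MEP2. Zinc genes rose in 7 and fell in 5 of 14 cases (median 0.07, adjusted p = 0.671), the zinc transporters ZRT1 and ZRT2 by 3.94-fold and 2.97-fold. Drug efflux genes rose in 11 and fell in 7 of 22 (median 0.07, adjusted p = 0.574), PDR12 by 4.43-fold. Cell wall integrity genes rose in 19 and fell in 10 of 32 (median 0.43, adjusted p = 0.0944), YPS1 by 5.18-fold and GAS5 by 4.23-fold.

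Fatty acid and phospholipid genes rose in 12 and fell in 7 of 21 cases (median 0.33, adjusted p = 0.447); INO2, an activator of phospholipid genes, fell 8.87-fold and ELO1 rose 4.08-fold. In the hypoxic list 9 of 18 rose and 6 fell (median 0.10, adjusted p = 0.763), with SUT1 up 8.12-fold and HEM13 (heme synthesis) down 4.46-fold. Peroxisome genes rose in 12 and fell in 11 of 24 cases (median 0.04, mean -0.03, test down, adjusted p = 0.986), POX1 rising 3.5-fold and CTA1 (catalase) falling 4.39-fold. In the environmental stress list 22 of 43 rose and 18 fell (median 0.07, mean -0.04, test up, adjusted p = 0.896), MRH1 rising 4.72-fold and GRE1 falling 6.31-fold. Oxidative stress genes rose in 16 and fell in 13 of 32 cases (median 0.06, adjusted p = 0.85), TKL1 rising 4.19-fold, and glycerol and osmotic genes rose in 8 and fell in 8 of 18 (median -0.06, adjusted p = 0.896), GPD1 rising 3.33-fold and GPP1 falling 3.08-fold. Unfolded protein genes rose in 9 and fell in 8 of 20 cases (median 0.0037, and -0.054 under quantile normalization, mean -0.05, test down, adjusted p = 0.941), with MPD1 up 4.12-fold and ERO1 down 4.04-fold.

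Genes of the G1 to S transition fell in 18 and rose in 9 of 32 cases (median -0.34, adjusted p = 0.259): SWI5 fell 4.18-fold and MCM6 2.88-fold, and the cyclin gene CLN3 rose 2.96-fold. Sporulation and meiosis genes fell in 13 and rose in 10 of 26 cases (median -0.25, mean 0.02, test down, adjusted p = 0.85); IME4 rose 7.91-fold, IME1 2.03-fold and SPO21 4.01-fold, while SSP2 fell 2.71-fold. HMRA1 fell by 1.35 on the log2 scale. Histone genes rose in 2 and fell in 4 of 9 cases (median 0.0053, and -0.056 under quantile normalization, mean -0.23, test down, adjusted p = 0.816), HHO1 falling 2.12-fold. Proteasome genes rose in 16 and fell in 15 of 33 (median 0.04, mean -0.05, test down, adjusted p = 0.934), and vacuole and autophagy genes rose in 12 and fell in 8 of 22 (median 0.32, adjusted p = 0.578), VMA5 rising 2.59-fold. Flocculation genes rose in 4 and fell in 6 of 14 cases (median -0.02, and 0.02 under quantile normalization, adjusted p = 0.873), PHD1 falling 4.87-fold. Thiamine and pyridoxine genes rose in 8 and fell in 6 of 17 cases (median 0.07, mean -0.06, test up, adjusted p = 0.913), SNO3 and SNZ3 falling 4.46-fold and 4.06-fold. Alternative sugar genes rose in 7 and fell in 5 of 14 (median 0.07, adjusted p = 0.941), MAL32 rising 2.47-fold and MPH2 falling 3.81-fold. Of the 4 auxotrophy genes 2 rose, 1 fell and 1 was not called (median 0.73, and 1.5 with background genes left out or at their bound, adjusted p = 0.466).

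Of 3470 probe sets without a listed gene that are not controls, 22 were at least 2-fold higher and 22 at least 2-fold lower in the evolved arrays, with all 6 arrays beyond both parental arrays.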
